A study of Drosophila melanogaster with 2 samples.

How the data were processed

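Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type Oregon R Drosophila melanogaster embryos. Per the labels' protocols, eggs were collected for 4.5 hours at 25 °C and aged for a further 5 hours, which gave embryos of 5 to 9.5 hours at stages 9 to 12. One library came from an immunoprecipitation with a guinea pig antibody against Deformed and the other from a mock immunoprecipitation with guinea pig IgG. Each group holds 1 library, so no test between libraries was possible, and p-values below describe how regions are placed along the genome, with regions as the units. They carry no information on the spread between embryo collections.

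Reads were aligned with Bowtie, per the submitters' processing notes. The Bowtie version and the genome build are not given in the sources used here. Enriched regions were called with MACS 1.4.0beta on the Deformed library against the IgG library, per the file headers, with a fragment length of 50 bases set in place of a fitted model, a tag size of 40 bases, an effective genome size of 120 Mb and local backgrounds estimated over 1000 and 10000 bases. MACS kept at most 4 tags at 1 position in the Deformed library and 3 in the control. That filter took the Deformed library from 20112283 to 15547495 tags, a loss of 22.7%, and the control from 13016695 to 12694075, a loss of 2.48%. The filtered Deformed library was therefore 1.22 times as deep as the control. The 2 deposited lists come from these same 2 libraries and differ in the p-value cutoff, 0.001 for the larger list and 0.0001 for the stricter list.

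Each deposited region carries a tag count, the whole number of tags that the authors' caller found in it. The deposited significance is a score, 10 times the negative log10 of the p-value, and its smallest values sit just above 30 in the larger list and 40 in the stricter list. The deposited fold enrichment is a ratio of tags at the summit to the local background, set by the authors' run of MACS. The deposited false discovery rate (FDR) is a percent. As MACS 1.4 defines it, this FDR is the number of regions found with the 2 libraries exchanged over the number found as labelled, at the same significance or better. All these values are the caller's own and are used here to describe and rank regions and, for tags, length and fold, to compare regions between places within a list. Tag counts of the control library in each region were not used here, so no background measured in the control is printed.

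The coordinates, printed as the files give them and counted from 1, are on a build that no source used here names. The gene table at hand belongs to Release 6 plus ISO1 MT. On chromosome arm 2R 802 of its 3649 genes start past the last deposited region, and on 3R 564 of 4226 do, so the regions are unlikely to be on that release, and no region was assigned to a gene. Several steps fixed before the data were examined were therefore not run: the location of regions relative to genes, the 21 gene lists, the sequence motifs and the look at the Deformed and reaper loci. The rule for named genes was to take Hox genes, cofactors and earlier-described targets, the genes at the 10 highest-ranked regions, the 10 genes with most regions and up to 4 genes per list. Only its parts on the highest-ranked regions and on the densest places could be kept, and these are named by position.

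The stricter list was the main list. Regions were ranked by score, then fold, then tags. The arm distribution was tested by 10000 random placements over the 6 arms in proportion to length, with the end of the last region of either list as the arm's length, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. Clustering was counted in 50 kb windows with at least 3 region centres, in place of genes, against 10000 placements on the same arm, one-sided. The centromere-proximal 2 Mb were taken as the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R. These windows, the 50 kb unit and all comparisons of medians between places were chosen after the data were seen. Medians were compared by permutation tests with 100000 resamples, two-sided, adjusted over the 12 comparisons made in each list. They include a background index, the tags per 100 bases of a region over its fold. Shares have exact (Clopper-Pearson) 95% intervals and tag counts exact Poisson 95% intervals, both of which cover counting error only. Overlaps were counted with bedtools 2.31.1 from 1 shared base upward. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

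The placement tests were also run on simulated data. With 500 placements per test and among 100 simulated lists of 1079 uniformly placed regions, the test of the proximal windows gave p below 0.05 in 1 list, that of chromosome 4 in 4 and that of clustering in 3. With 200 regions planted in the proximal windows, the proximal test did so in 100 of 100 lists and the clustering test in 99. The test of chromosome 4, where nothing was planted, did so in 8. Alternatives were the larger list, the higher-scoring 50% of the stricter list, merging of nearby regions, other overlap rules, other window sizes and the number of genes per arm as the expectation.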

Results

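Deformed is a Hox transcription factor that gives the mandibular and maxillary segments of the fly head their identity. The study asked which stretches of the genome it occupies in embryos in which these segments are forming. The data compared 1 Deformed ChIP library, of 15547495 tags after duplicate filtering, with 1 mock IgG library of 12694075 tags, from wild-type embryos of 5 to 9.5 hours. The values are those of the authors' region lists, in which each region has a position, a tag count, a fold enrichment over local background and a significance score. There were no replicates, so none of the values below has a replicate error. In vivo reporter tests of bound regions, which the series also mentions, were not analysed here.

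At a p-value cutoff of 0.0001 the Deformed antibody gave 1079 enriched regions over the IgG control, and at 0.001 it gave 3898. The 1079 stricter regions were short and shallow, with a median length of 204 bases (quartiles 167.5 and 291.5), a median of 27 tags (quartiles 21 and 51) and a median fold of 5.04 (quartiles 4.44 and 5.79). The larger list had a median length of 201 bases, 22 tags and a median fold of 4.48. A count of 27 tags has a 95% Poisson interval of 17.8 to 39.3, so tag counts of typical regions are known only coarsely. The folds rest on tags at the summit, and their error was not estimated. The stricter regions held 0.571% of the filtered Deformed tags (95% exact interval 0.568 to 0.575) on 345 kb, which is 0.288% of the effective genome, and a mean of 82.3 tags per region. The larger list held 1.02% of the tags on 970 kb, 0.808% of the genome, and a mean of 40.5 tags per region. The share of tags over the share of the genome was thus only 1.99 in the stricter and 1.26 in the larger list. These ratios weigh regions with many tags most, as the stricter mean of 82.3 tags beside a median of 27 shows. A stricter region of median length and median tags would hold about as many tags per base as the effective genome does on average. A larger-list region of median length and median tags would hold fewer. The deposited folds compare the summit with a background, so they are a different measure from these ratios over whole regions. The gap between folds and ratios was not explained here.

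The authors' FDR separated a small set of regions from the rest. An FDR of 0% was given to 9 regions in each list, of which 8 were shared. The 2R region at 2320050 to 2320896 had it in the stricter list only: in the larger list the same place, called from 2319983, had a score of 553.67 and an FDR of 18.18%, and the 2R region at 94092 to 100672 had 0% instead. In the stricter list 11 more had an FDR between 9.09% and 80%, and the other 1059 regions, 98.1% of the list, had an FDR of 100%. In the larger list 3877 of 3898 regions, 99.5%, had an FDR of 100%. The product of the FDR and the rank was a whole number to within 0.01 for each of the 20 stricter regions under 100%, which gives the number of regions called in the opposite direction, control over Deformed. No such region reached the score of the 9 strongest Deformed regions. By the region ranked 20, with a score of 324.68, there were 16 of them, and by the region ranked 21, with a score of 319.24, at least 21.

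**Figure D1:**
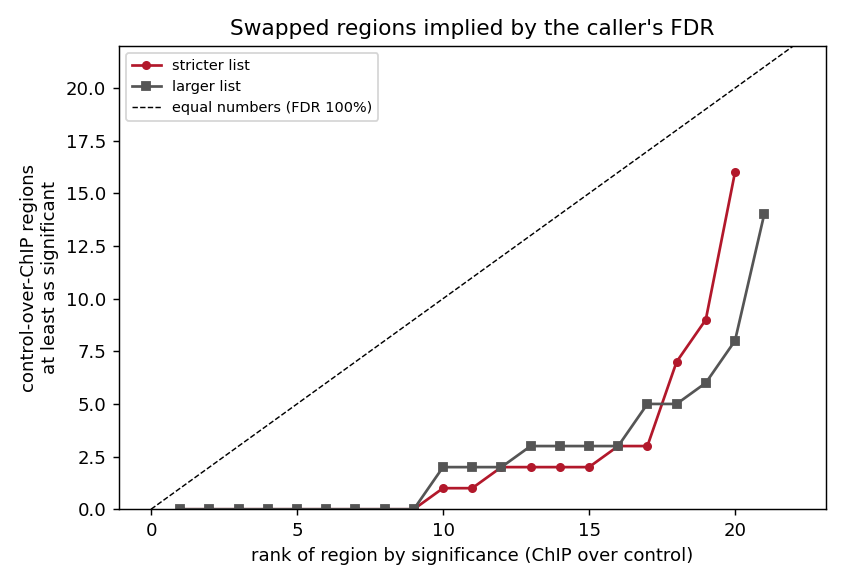
Number of control-over-Deformed regions at least as significant as each Deformed region (vertical axis), as implied by the authors' FDR, against the rank of the Deformed region by significance (horizontal axis), for the stricter (circles) and the larger list (squares). Both curves stay at 0 through rank 9 and then climb to 16 at rank 20 and 14 at rank 21, and the dashed line marks equal numbers, an FDR of 100%.

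The region with the highest score and the highest fold lay on chromosome X at 2683986 to 2687295. It was 3310 bases long, held 1698 tags (95% Poisson interval 1618 to 1781) and was enriched 25.21-fold. Another X region 2.65 kb away, at 2689944 to 2690810, ranked 3 with 328 tags (293 to 365) and a fold of 16.34. No other region of either list had a fold above 12, and no region of the larger list lay in the gap between them. In the stricter list 150 regions had at least 100 tags, and the highest fold among these, the pair left out, was 9. These values count tags by sequence, and tags from embryo chromatin were not told apart here from tags of any other DNA of the same sequence, such as a plasmid, so the folds of the pair are not a measure of binding by themselves.

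The other 7 regions with an FDR of 0% in the stricter list held 630 to 4708 tags, at folds from 2.35 to 6.69. Of these, 4 were neighbours on 2R. The one at 2315369 to 2319409, ranked 2, held 4708 tags at a fold of 2.49, and that at 2285758 to 2289963, ranked 4, held 3534 tags at 2.69. Those at 2307224 to 2309065 and 2320050 to 2320896 had 931 and 630 tags at folds of 4.80 and 4.83. A further 2R region at 8750975 to 8754620 held 2159 tags at a fold of 3.28. The remaining 2 lay near the centromeric ends of their arms, on 3L at 24446202 to 24447708 with 651 tags at a fold of 6.69, and on X at 21801725 to 21803438 with 1611 tags at a fold of 2.35. The region ranked 10, on chromosome 4 at 612468 to 613308, had 513 tags, a fold of 5.40 and an FDR of 10%. Away from the centromeric ends, the autosomal region on 3L at 18384351 to 18385033 ranked 16 with only 132 tags (110 to 157), a fold of 8.83 and an FDR of 18.75%. The limit on the source of tags given for the X pair holds for this and every other region. No annotation on the build of these positions was used here, so the genes at these places are not named.

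**Figure D2:**
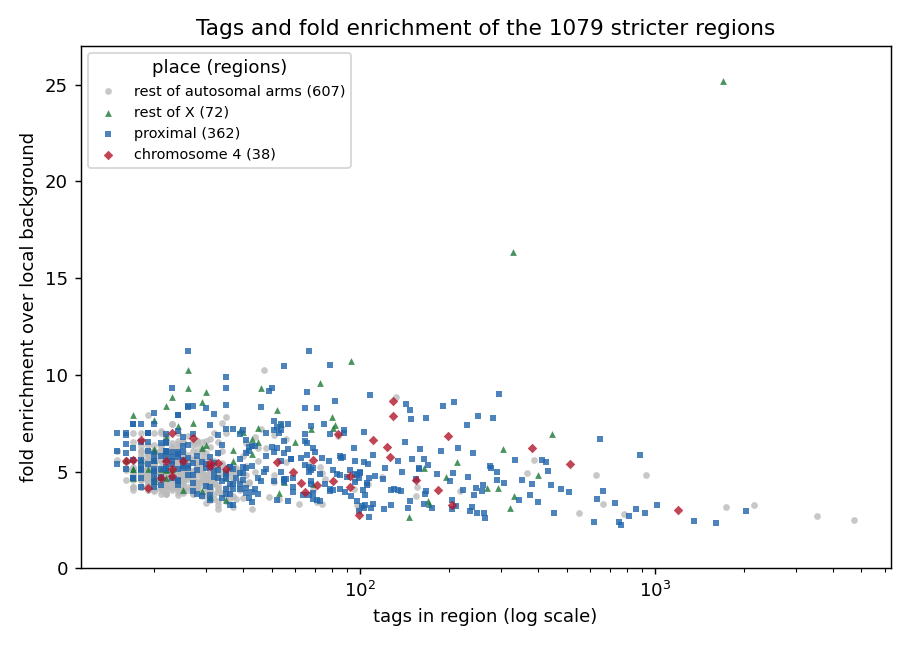
Fold enrichment over local background (vertical axis) against tags per region (horizontal axis, log scale) for the 1079 regions of the stricter list, one point per region, marked by place on the genome. A pair of X regions stands apart at 25.21-fold and 16.34-fold, while the regions with most tags have folds near 2.5.

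The stricter regions were concentrated at the centromeric ends of 4 of the 5 long arms. The last 2 Mb before the centromere held 362 of the 1041 stricter regions on these arms, 34.8%, against 88.2 expected from random placement, a 4.11-fold excess (two-sided placement test, n = 1041 regions, p = 0.0002, the smallest the draws allow). The excess was 5.44-fold on 3L (122 regions), 5.34-fold on X (66), 4.41-fold on 2R (86) and 3.61-fold on 2L (73), each with an adjusted p of 0.00025. The arm 3R did not show it, with 15 regions against 13.6 expected (n = 190 regions, adjusted p = 0.777). The excess over all 5 arms was smaller in the larger list, at 2.14-fold, and after merging regions less than 10 kb apart, at 2.43-fold. Among the larger list's regions below a score of 40 it was 1.45-fold, and 2L, at 1.19 (n = 590 regions, p = 0.187), joined 3R in not passing the test. The opposite, telomeric 2 Mb held 52 regions. Random placement over the whole arms gave 88.1 (two-sided placement test, n = 1041 regions, p = 0.0002), an expectation that includes the proximal regions. Random placement outside the proximal windows gave 61.9, and the difference did not pass the test (n = 679 regions, p = 0.208). In the larger list the telomeric ends held 214 against 285 expected (n = 3140 regions, p = 0.0002). These placements, and the medians and groups below, describe the called list, in which 98.1% of stricter regions had an FDR of 100%. Of the 20 stricter regions below 100%, 9 were proximal. For the rest, control-over-Deformed regions of the same score or better were at least as many. Their positions were not examined, so whether they show the same placement was not tested.

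Proximal regions of the stricter list differed in length and tags from the 607 regions on the rest of the autosomal arms. Their median length was 278 against 189 bases and their median tag count 54 against 23 (adjusted p = 1.5e-05 for each, permutation test, from the smallest p the resamples can give). Their median fold was 5.14 against 4.92, a difference of 0.22 (permutation test, adjusted p = 0.0148). In the larger list the proximal median was 31 tags against 22 (permutation test, adjusted p = 2.4e-05). These tests treat regions as independent, although after merging stricter regions less than 10 kb apart only 148 were proximal. The p-values of the medians may therefore be too small, and medians were not tested on merged regions. Proximal regions were 33.5% of the stricter list and held 49.7% of its tags, and they made up 2 of its 10, 9 of its 20, 28 of its 50 and 70 of its 100 highest-ranked regions. The 4 neighbouring 2R regions above lie just outside the 2 Mb window, and with a 3 Mb window 6 of the 10 and 78 of the 100 highest-ranked regions were proximal.

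**Figure D3:**
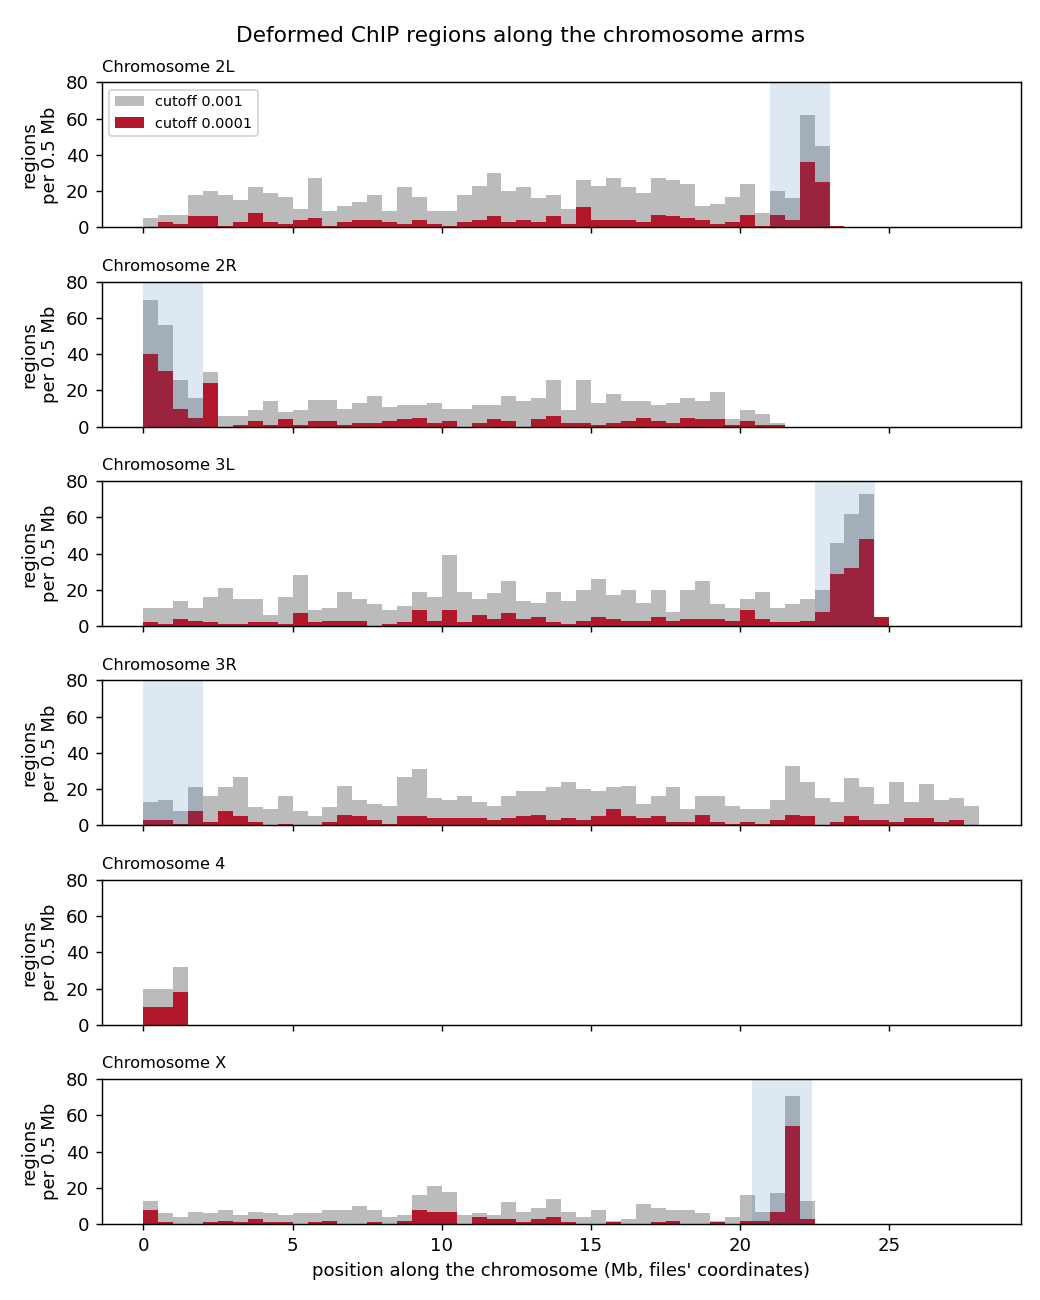
Number of regions per 0.5 Mb (vertical axis) along each chromosome arm (horizontal axis, Mb in the files' coordinates), for the larger list (grey) and, drawn over it and also counted from 0, the stricter list (red), with the proximal 2 Mb shaded blue. Counts rise in the shaded ends of 2L, 2R, 3L and X, up to 54 stricter regions per 0.5 Mb on X, and not on 3R.

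Chromosome 4, the small and largely heterochromatic autosome, carried more stricter regions than its length predicts, and X carried fewer. Chromosome 4 held 38 of 1079 stricter regions, 3.52% against 1.10% of the length, a 3.20-fold excess (placement test, n = 1079 regions, adjusted p = 0.0004). With the number of genes per arm as the expectation the excess was 5.46-fold (n = 1079 regions, adjusted p = 0.0004). By length it was 1.68-fold in the larger list (n = 3898 regions, adjusted p = 0.0006), and among that list's regions below a score of 40 it was 1.20 and did not pass the test (n = 2580 regions, adjusted p = 0.337). The stricter regions of chromosome 4 had a median of 67 tags and a median fold of 5.42, against 23 tags and 4.92 on the rest of the autosomal arms (permutation test, adjusted p = 1.5e-05 and 0.00383). Its median in the larger list was 25 tags against 22 (permutation test, adjusted p = 0.0158). X held 138 regions, 12.8% against 18.6% of the length, or 0.69 of the expected number (n = 1079 regions, adjusted p = 0.0004). In the higher-scoring 50% of the stricter list the X deficit did not pass the test, with 95 regions against 100.6 expected, a ratio of 0.94 (n = 540 regions, adjusted p = 0.686). Outside the proximal 2 Mb the X ratio was 0.54, with 72 regions against 132.7 expected (n = 717 regions, adjusted p = 0.0006). Those 72 X regions had a median fold of 6 and a median of 36 tags, both above the autosomal values (permutation test, adjusted p = 1.5e-05 for each). In the larger list the tags went the other way, with a median of 19 on X against 22 (permutation test, adjusted p = 6.86e-05), while the fold stayed above, at 4.67 against 4.38 (permutation test, adjusted p = 9e-05). Of the other arms, 3L was above its share at 1.25 (n = 1079 regions, adjusted p = 0.0006) and 3R below at 0.76 (adjusted p = 0.0004), while 2L at 1.12 and 2R at 1.09 did not pass the test (adjusted p = 0.0734 and 0.206). Arm 2L did pass in the larger list, at 1.17 (n = 3898 regions, adjusted p = 0.0004), and 3R turned to 1.02 there (adjusted p = 0.594). Below a score of 40 the 3R ratio was 1.11 and passed the test in the opposite direction (n = 2580 regions, adjusted p = 0.0045). Neither the 3L nor the 3R difference passed once the proximal windows were left out, with ratios of 1.04 and 1.04 (n = 717 regions, adjusted p = 0.687 for each).

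The stricter regions formed more groups of 3 or more than random placement gives. At least 3 region centres fell in 71 windows of 50 kb, against 30.8 expected and at most 49 in any of 10000 placements (one-sided, n = 1079 regions, p = 0.0001, the smallest the draws allow). Of these windows 45 were proximal, 18 lay on the rest of the autosomal arms, 5 on chromosome 4 and 3 on the rest of X. The densest were X 21600001 to 21650000 with 14 regions and a median fold of 4.56, 2R 2150001 to 2200000 with 13 regions and a median fold of 5.33, and X 21800001 to 21850000 with 12 regions and a median fold of 5.47. Next came X 21750001 to 21800000 and 2L 22250001 to 22300000 with 11 each. Windows with 10 regions were 2R 150001 to 200000, 3L 23850001 to 23900000, X 21650001 to 21700000 and 2R 850001 to 900000. Outside the proximal windows and chromosome 4, 21 windows held at least 3 regions against 9.54 expected (n = 679 regions, p = 0.0006). The higher-scoring 50% of the stricter list gave 46 windows against 5.80 expected, a ratio of 7.93 (n = 540 regions, p = 0.0001). The count was near the expected number for windows with at least 2 stricter regions, 189 against 186 (n = 1079 regions, p = 0.385). It was also near it in the larger list, where 549 windows held at least 3 regions against 545 expected (n = 3898 regions, p = 0.393). Random placement already fills many windows in these settings, so neither count says much on clustering.

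The 2 lists were not nested. Of the 1079 stricter regions 1033, or 95.7% (95% exact interval 94.4 to 96.9), overlapped a region of the larger list, and 509 had the same start and end there. The other 46 had a median of 19.5 tags, but they included a 3471-base region, and the highest score among them was 190.11. In the other direction, 1318 regions of the larger list had a score of at least 40, the value of the stricter cutoff, and 406 of these, 30.8%, overlapped no stricter region. Those 406 had a median fold of 4.29, against 5.11 for the 912 that did overlap. The longest region of the larger list, on 2R at 94092 to 100672, had 1706 tags, a score of 728.37 and an FDR of 0%. The stricter list kept only its part from 94092 to 95675, with 413 tags, a score of 200.01 and an FDR of 100%.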

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

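The alternatives with the proximal windows, the score limit of 40, merging at 10 kb, genes per arm, the 50 kb unit of clustering and the medians by place were chosen after seeing the data. Of 65 recomputed values with a test, 41 kept their direction and side of the threshold. Of 18 without a test, 14 stayed within 1.5 times a count or within a counting interval. Most of these were tag counts of the 10 highest-ranked regions, read from the other list of the same libraries. Another was the removal of unplaced sequences, which left all 1079 regions. Such outcomes were largely fixed in advance and say little on robustness. The count of 1079 regions became 3898 in the larger list, 540 in the higher-scoring 50% of the stricter list by construction, and 679 without the proximal 2 Mb and chromosome 4. The shared fraction fell to 94.0% when 50% of both lengths had to overlap. The proximal excess over all 5 arms together held in every alternative run, from 1.45-fold in the larger list below score 40 to 6.46-fold with a 1 Mb window. Below score 40 that of 2L did not pass, with 61 regions against 51.3 expected, at 1.19 (placement test, n = 590 regions, p = 0.187). The chromosome 4 excess rose to 5.46 with genes per arm, fell to 1.68 in the larger list and did not pass below score 40, at 1.20 (adjusted p = 0.337, placement test, n = 2580 regions), nor did the X deficit in the higher-scoring 50%, at 0.94 (adjusted p = 0.686, placement test, n = 540 regions). The count of clustered windows rose to 7.93 times the expected number in the higher-scoring 50%. It was near the expected number with at least 2 regions per window, at 1.02, and in the larger list, at 1.01. In these 2 settings random placement fills many windows, so the count says little on clustering. Arm 2R moved from above to below 1: 0.98 in the larger list, 0.94 below score 40, 0.96 without the proximal windows, 0.97 after merging at 10 kb, and 0.93 (stricter) and 0.84 (larger) with genes as the expectation, of which only 0.84 passed the test (n = 3898 regions, adjusted p = 0.00024). Arm 3R moved from below to above 1: 1.02 in the larger list, 1.04 without the proximal windows and 1.11 below score 40, where it passed the test in the opposite direction (n = 2580 regions, adjusted p = 0.0045). Its deficit also did not pass after merging at 10 kb, at 0.99, or with genes and the larger list, at 0.99. Arm 2L passed in 4 alternatives: 1.17 in the larger list, 1.20 below score 40, 1.21 after merging and 1.13 with genes and the larger list. On the rest of X the medians over the autosomal ones moved below 1 in the larger list, each past the test: 0.86 for tags, 0.88 for length and 0.97 for the background index. Except where the construction shows it, the cause was not tested. No paired analysis was possible because each group has 1 library. The arm lengths without unread bases were not run, nor were the alternatives for gene location, gene lists and motifs. Depth limits typical regions, at about 27 tags each.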

Other observations

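All tests of explanations in this section were chosen after the result was seen.

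Beyond the places named in the report, the stricter list held a group of regions at the telomeric tip of X. The window from X 1 to 50000 had 7 regions with 1856 tags together and a median fold of 3.71. The 2 strongest lay at 9090 to 10371, with 400 tags at a fold of 4.84, and at 11931 to 12759, with 331 tags at a fold of 3.71. Apart from the strongest X pair, regions with a fold above 10 held 26 to 93 tags, among them X 6101094 to 6101593, of 500 bases with 93 tags at 10.70-fold, and 2R 2350070 to 2350285, of 216 bases with 47 tags at 10.23-fold. On chromosome 4 the window from 600001 to 650000 had 7 regions with a median fold of 6.22, including the regions ranked 10 and 12.

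Several tests rest on a feature of the deposited folds. Many folds fall on a ladder with steps of 0.467, which is what whole tag numbers over 1 fixed background would give: 22.6% of the stricter and 29.5% of the larger list lie on it to within 0.006, where evenly spread values would give 2.57%. The step was picked as the one that fits most regions of these same lists, so the totals are raised by that choice. A fold off this ladder was read as a sign that the local background, not the genome-wide one, was used. That reading is an inference from the values, since the headers do not record it. The headers also speak against it. Spread over the 120 Mb effective genome, 15547495 Deformed or 12694075 control tags give more tags per 50 bases than a step of 0.467 implies. The ladder therefore does not match the genome-wide background that these values give, and what sets its step was not resolved. The ladder shares below are printed as values only and cannot bear on a cause. The background index, the tags per 100 bases of a region over its fold, is a separate and indirect measure of local background.

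Whether the excess of regions in the centromere-proximal 2 Mb reflects a raised local background, such as repeated or collapsed sequence gives, could not be decided. In the stricter list 12.2% of proximal regions lay on the ladder against 28.8% on the rest of the autosomal arms (Fisher's exact test, p = 7.02e-10), and in the larger list 22.3% against 27.9% (p = 0.00333). The median background index was above the autosomal 2.49 in both lists, at 3.45 and 2.86 (permutation test, adjusted p = 1.5e-05 and 2.4e-05). Neither measure can decide, because the deposited fold is already divided by the local background. Binding of Deformed in these windows could give the same values. The index is made from tags of the Deformed library, length and fold, without control tags. A 2.43-fold excess stayed after regions less than 10 kb apart were merged (placement test, n = 727 merged regions, p = 0.0002). Separate counting of such close regions was thus not the whole cause. Merging at 10 kb does not join neighbours further apart, and the test treats merged regions as independent. Wider clusters as a cause therefore stay open. Binding of Deformed in pericentromeric chromatin is untested and stays open, as does mapping, since no tag counts of the control were used here, and no test explained the lack of an excess on 3R.

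The excess of regions on chromosome 4 could have the same source, but the lists differ. In the stricter list 10.5% of its regions lay on the ladder against 28.8% on the rest of the autosomal arms (Fisher's exact test, p = 0.0142), and in the larger list 27.8% against 27.9% (p = 1). The background index was higher in both lists, at 3.96 and 2.81 against 2.49 (permutation test, adjusted p = 1.5e-05 and 6.86e-05). With the ladder not tied to the genome-wide background, a raised background cannot be told apart from binding there, which was not tested. A 2.19-fold excess stayed after merging at 10 kb (placement test, n = 745 merged regions, adjusted p = 0.0126). Close regions counted separately were thus not the whole cause, while wider clusters stay open.

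The deficit of regions on X may come from lower tag coverage, since male embryos carry a single X, although the labels do not give the sex of the embryos. In the larger list 59.2% of X regions outside the proximal window lay on the ladder, against 27.9% on the rest of the autosomal arms (Fisher's exact test, p = 3.79e-28). The stricter list showed 29.2% against 28.8% (Fisher's exact test, p = 1). The background index was also split, above the autosomal 2.49 in the stricter list at 2.71 and below it in the larger at 2.42 (permutation test, adjusted p = 0.00203 and 0.0294), so coverage cannot be told apart from other sources. A smaller number of genes on X does not account for all of it, because the ratio stayed at 0.84 of the number expected from genes per arm (n = 1079 regions, adjusted p = 0.0333) and at 0.72 in the larger list (n = 3898 regions, adjusted p = 0.00024).

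The pair of X regions at 25.21-fold and 16.34-fold was not weighed. Whether its tags, and those of the 3L region ranked 16 or of any other region, came from embryo chromatin was not tested. Other DNA of the same sequence, such as a plasmid, was not told apart.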
